A study of Mus musculus with 15 samples.

How the data were processed

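Tumours grown from GL26 glioma cells injected into the brains of C57BL6 mice were profiled as total RNA on 15 Affymetrix mouse arrays, 1 per sample. Per the labels, RNA was extracted with Trizol and labelled with biotin by the standard Affymetrix procedure, and the deposited values are signal intensity, on a linear scale as judged from their range. The deposited intensity table holds 45101 probe sets, and the mean of each array after trimming 2 percent of the values at each end was nearly equal on all arrays, as checked in the table. The summary method and its version, the date of each array and the number of animals are not given in the sources used here. All 15 columns were used.

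Samples were grouped by the labels as wild type (4 arrays), nude (5), vaccinated (4) and old wild type (2). The comparisons were nude, vaccinated and old wild type each against wild type, and vaccinated against nude. No signal was below 0; 32 was added to each and log2 was taken. The medians of the arrays then ranged from 5.96 to 6.23, a range of 0.27 that exceeded the limit of 0.2 set for leaving the scale alone, so the arrays were quantile normalised. The 64 control probe sets were left out. Of the other probe sets, 34945 named 1 gene, 932 named several genes and 9160 none; the latter 2 kinds were not tested. Of the probe sets with 1 gene, 34741 matched a RefSeq gene by its ID. Each gene was represented by its probe set with the highest mean, which left 18193 genes, of which 9010 had more than 1 probe set. No filter on dim genes was applied. Genome positions are not printed because no build is named for the arrays.

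Each gene was fitted with 1 mean per group by limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend), with 11 residual and 4.52 prior degrees of freedom. Adjusted p values are Benjamini-Hochberg over all genes of a comparison, and a gene passed under 0.05. The 29 gene lists, 492 entries in all, covered immune and brain cell types, antigen presentation, interferon responses, chemokines, checkpoints, cell division, metabolism, matrix, stress and sex-linked genes. A list needed 4 measured members. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, then with an estimated correlation and with fry. The mean of a list's members on each array was compared between groups with a 2-sided exact permutation test over all splits, and over splits within labelling runs. Counts adjusted over the list alone use the p values of its members only.

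The named genes were, per comparison, up to 8 of the largest rises and falls among genes that passed without overlap between arrays, or the 3 smallest p values in a direction where none passed. Up to 4 members with the smallest p and all members against the direction were taken from each list that passed or that the text describes, and Foxn1, Prom1, Nes, Sox2, Gfap, Dct, Ptprc, Cd3e, Cd4 and Cd8a in every comparison. Trbc1 was in that rule too but was not measured as a gene. The deposited signals of C1qa, C1qb, Lyz2, Ctss, Tyrobp and Csf1r are given as genes chosen after their values were seen, as are the probe set medians of Vim and other genes with high signals. The groups, the comparisons, the lists, this rule, the tests and most alternatives were chosen before the data were examined. The labelling run, found from the 18S control probe sets, was added after seeing the data, as a covariate and as a restriction to either run. The log2 difference of the 3' and 5' actin control probe sets, a sign of RNA quality, was likewise added after seeing the data, as a covariate.

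Alternatives tried were offsets of 1 and 128, deposited scaling, centring on the median, the mean of a gene's probe sets, every probe set, the brighter genes, a model with only the groups compared, array weights, no intensity trend, a threshold of 0.01, a 2-fold minimum, the mean of neuron and oligodendrocyte genes as a covariate, title numbers up to 9 against the rest, a replicate block and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

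The steps were tested on simulated data with 200 changed genes among 18193, in 10 simulations per comparison. At 1.5-fold, 2-fold and 4-fold the share recovered was 33.4, 83.9 and 99.5 percent in nude against wild type, and 27.5, 78.5 and 99.5 percent in vaccinated against wild type. It was 14.5, 60.1 and 98.0 percent in old wild type against wild type, and 34.6, 84.5 and 99.7 percent in vaccinated against nude. False calls averaged 5.7, 6, 6.1 and 9.1 per simulation in the same order, and 0 calls had the wrong direction. A list of 20 genes shifted by 0.4 was found in 10 of 10 simulations of each comparison, with 0 false lists. The simulated noise was independent between genes and arrays, and the simulated lists were random genes. The simulations therefore say nothing about false lists when members are correlated or arrays differ by run. The folds were set on the scale with the offset, where the same fold in the signal of a dim gene is smaller.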

Results

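RNA was measured on 15 arrays from tumours that grew in the brains of C57BL6 mice after injection of GL26, a mouse glioma cell line. Of these arrays, 4 came from untreated wild type mice and 5 from nude mice, whose mutated Foxn1 gene leaves them without a thymus and with few T cells. Another 4 came from wild type mice given a dendritic cell vaccine against GL26, and 2 from untreated wild type mice aged 10 months, called old wild type. The titles of the other arrays give no age. The groups allow a tumour to be compared between hosts with and without a thymus, with and without the vaccine, and of different age. The median deposited signal of an array lay between 30.3 and 43.2, and 8961 of 18193 genes had a median signal above 100.

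Values are given as log2(signal + 32), a scale on which a signal of 0 equals 5. A value after ± is the standard error (SE) of a log2 fold change, or the standard deviation (SD) of a group mean. The number of arrays limits the precision: the median SE over genes was 0.17 in nude against wild type and 0.21 in old wild type against wild type. Nothing in the labels says that replicates came from separate animals, so each p measures the spread between samples.

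Control probe sets for 18S ribosomal RNA split the arrays by the number in their titles. Their signal was 1838 to 2678 on the 9 arrays numbered 1 to 11 and 62.7 to 122 on the 6 arrays numbered 12 to 19, a 22.1-fold difference. These sets are called labelling runs here, although the labels name no run. Run 1 to 11 held 2 wild type, 3 nude, 2 vaccinated and 2 old wild type arrays. Run 12 to 19 held 2 wild type, 2 nude and 2 vaccinated arrays and no old wild type array. Arrays of the same group correlated across probe sets with a median r of 0.984 within a run and 0.965 between runs, and arrays of different groups in the same run with 0.978. The log2 difference of the 3' and 5' actin control probe sets, which rises as RNA degrades, was 0.202 to 0.247 on vaccinated, 0.266 to 0.291 on old wild type, 0.250 to 0.536 on wild type and 0.303 to 0.571 on nude arrays. It thus parted every vaccinated array from every other array, though the nearest wild type array was close (0.250 against 0.247). The same difference of the Gapdh control probe sets did not part them. It was -0.314 to -0.263 on vaccinated arrays and -0.393 to -0.254 on the others. The actin difference was used as a covariate after it was seen, and the Gapdh difference was not used.

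Sox2, a transcription factor of neural stem cells, measured 12.01 ± 0.18 (SD, n = 4) in wild type, 12.08 ± 0.05 (SD, n = 5) in nude, 12.08 ± 0.13 (SD, n = 4) in vaccinated and 11.92 ± 0.26 (SD, n = 2) in old wild type tumours. Nes, an intermediate filament of neural progenitors, measured 10.31 ± 0.24 (SD, n = 4) in wild type, 10.46 ± 0.45 (SD, n = 5) in nude, 10.12 ± 0.16 (SD, n = 4) in vaccinated and 9.92 ± 0.28 (SD, n = 2) in old wild type tumours. Vim, another filament, had a median signal of 12331 over the 15 arrays. Transcripts of T cells were near the floor: Cd3e, a chain of the T cell receptor complex, had a median signal of 26.3 and Cd4 3.7. So was Ptprc, the pan-leukocyte antigen CD45, at 7.3. Other host cell lists were low too, with median signals of 18.75 for macrophages and microglia, 16.7 for endothelial cells and 3.7 for erythroid cells. The oligodendrocyte and astrocyte lists stood higher, at 129.8 and 83.8. The share of host cells in the samples was not tested. Of 17 measured T cell genes, 16 never exceeded a signal of 100 on any array.

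Nude against wild type tumours addressed the host without a thymus. Foxn1 itself, the gene mutated in nude mice, measured 5.87 ± 0.19 (SD, n = 5) in nude and 5.59 ± 0.34 (SD, n = 4) in wild type tumours, a log2 fold change of 0.27 ± 0.17 (limma adjusted p = 0.989). A second Foxn1 probe set gave -0.20, and both lay near the floor, so the gene checked no label. Genes of cell division were lower in nude tumours as groups. The DNA replication list had a mean log2 fold change of -0.51, with 21 of 21 members lower and 4 of 5 nude arrays below the wild type mean. The mitosis list had a mean of -0.39, with 19 of 19 members lower and again 4 of 5 nude arrays below. The type I interferon response list was higher, with a mean of 0.36, 19 of 20 members higher and 4 of 5 nude arrays above the wild type mean.

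These 3 of 29 lists passed camera, limma's test of a list against the other genes, with adjusted p = 1.38e-12 for DNA replication, 6.02e-10 for mitosis and 6.55e-05 for type I interferon. None of the 3 passed when camera estimated the correlation between members: DNA replication had adjusted p = 0.553 with an estimated correlation, mitosis adjusted p = 0.614 with an estimated correlation and type I interferon adjusted p = 0.82 with an estimated correlation. No member passed over all genes, and 0 passed adjusted over the list alone. In 2-sided exact permutation tests of the list means, DNA replication had p = 0.127 and mitosis p = 0.135, with an adjusted p of 0.776 over the 29 lists for both. Type I interferon had exact permutation p = 0.389 (adjusted 0.806), and the smallest p that the 126 splits can give is 0.00794.

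Among replication genes, the log2 fold change of Gins2 was -0.44 ± 0.15 and that of Gins1 -0.67 ± 0.25; both belong to the complex that unwinds DNA at the fork. Ccne1, the cyclin that drives entry into S phase, had -0.64 ± 0.22, and Rfc4, part of the loader of the replication clamp, -0.57 ± 0.23. Among mitosis genes, the kinase Aurkb had -0.68 ± 0.23, the kinetochore motor Cenpe -0.56 ± 0.22, Birc5 -0.44 ± 0.20 and Ube2c, which helps to degrade cyclins, -0.34 ± 0.14. Of the interferon genes, the antiviral Rsad2 had 0.82 ± 0.33, Ifit1 0.71 ± 0.38, Rtp4 0.70 ± 0.39 and the regulator Irf7 0.47 ± 0.30. Ifit2 went against the list with -0.11 ± 0.24.

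Both cell division lists kept their direction within each run: DNA replication was -0.24 in run 1 to 11 and -0.83 in run 12 to 19, and mitosis -0.26 and -0.56. They were -0.50 (camera adjusted p = 2.09e-11) and -0.38 (3.24e-09) with the run as a covariate. The direction in run 1 to 11 rested on nude replicate 2, at 9.04 for DNA replication and 9.71 for mitosis. For DNA replication nude replicates 1 and 3 measured 10.265 and 10.36, and the wild type arrays of that run 10.317 and 9.95. For mitosis they measured 10.494 and 10.634, and the wild type arrays 10.65 and 10.427. The mean shift of both lists in that run was -0.25 ± 0.47 (SE). Over both runs, the DNA replication shift without nude replicate 2 was -0.32 and still passed. With the actin difference as a covariate the DNA replication shift was -0.52 (camera adjusted p = 6.61e-16), the mitosis shift -0.40 (1.34e-11) and the type I interferon shift 0.36 (0.000223). Type I interferon turned between runs, with -0.10 in run 1 to 11 and 0.83 in run 12 to 19, and 0.35 with the run as a covariate (camera adjusted p = 0.000425). Its shift was 0.07 without wild type replicate 3 (camera adjusted p = 0.631), 0.23 without nude replicate 3 (0.0647) and 0.64 without wild type replicate 1 (8.99e-11).

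No single gene passed limma in nude against wild type tumours, with or without the run as a covariate, and the smallest adjusted p was 0.989. Unadjusted p values under 0.05 numbered 759 of 18193 genes. Run 12 to 19 alone, with 2 arrays a side, gave 11 genes higher and 8 lower, and run 1 to 11 alone gave 0 and 0. The smallest p values that did not pass belonged to Fam217b (0.60 ± 0.15), Fads2b (0.37 ± 0.10), Col9a1, a cartilage collagen chain (0.91 ± 0.25), A930009L07Rik (-0.53 ± 0.11), Prl8a9 (-0.35 ± 0.08) and Rasd1 (-0.57 ± 0.14). In T cell transcripts no difference was detectable at these signals: the list mean was -0.05 (camera adjusted p = 0.627), with Cd3e at -0.28 ± 0.25, Cd4 at -0.03 ± 0.08 and Cd8a at -0.24 ± 0.28. Cd28, a costimulatory receptor, measured 0.45 ± 0.14 with limma adjusted p = 0.989. The chemokine Ccl5 had 0.83 ± 0.31 (limma adjusted p = 0.989). Gfap, a filament of astrocytes, measured 0.32 ± 0.34, Prom1 0.10 ± 0.10 and Ptprc 0.03 ± 0.15, and none of these passed.

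**Figure D1:**
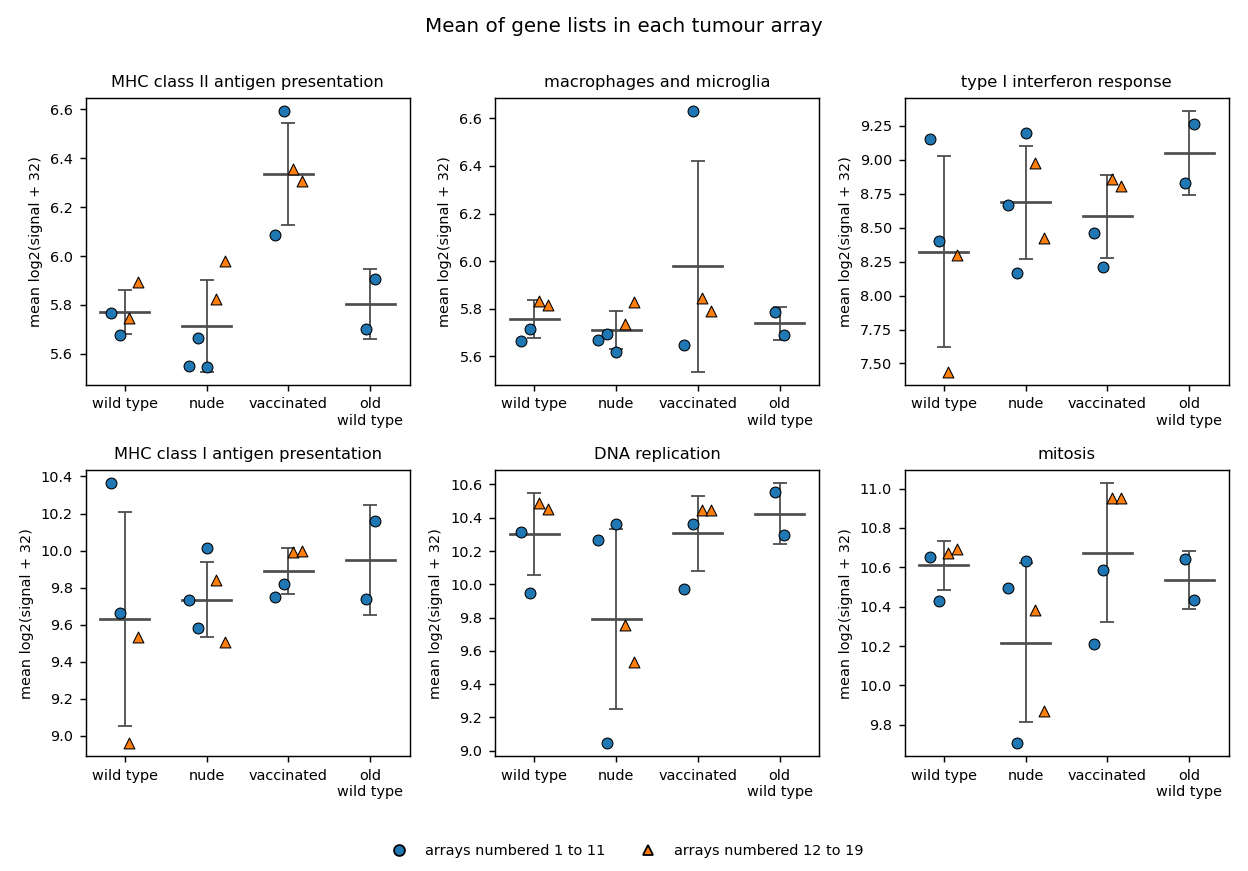
Mean log2(signal + 32) of the members of each list on each array, by group; points are arrays (circles numbered 1 to 11, triangles 12 to 19), lines are group means and bars are SD. The DNA replication list averaged 10.30 in wild type, 9.79 in nude, 10.31 in vaccinated and 10.42 in old wild type tumours.

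Vaccinated against wild type tumours addressed the vaccine. Genes of MHC class II, the molecules that present peptides to CD4 T cells, were higher after the vaccine. H2-Eb1, the beta chain of H2-E (Entrez Gene 14969), rose by 0.85 ± 0.10 on the scale with the offset, from 5.42 ± 0.12 (SD, n = 4) to 6.27 ± 0.15 (SD, n = 4). It was the 1 gene of 18193 that passed limma (adjusted p = 0.00582; 907 genes had an unadjusted p under 0.05), and 0 genes fell. Its deposited signal was 31.8 to 53.7 on the 4 vaccinated arrays and 3.2 to 13.7 on the other 11, so the gene was dim in every group and the size of its rise depended on the offset (0.32 with the larger one, 2.01 with an offset of 1). The class II list was higher by a mean of 0.56, at 6.33 ± 0.21 (SD, n = 4) against 5.77 ± 0.09 (SD, n = 4), with 8 of 9 members higher and all 4 vaccinated arrays above every wild type array.

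Camera gave the class II list an adjusted p of 1.79e-06, and it also passed with an estimated correlation (adjusted p = 0.0438 with an estimated correlation) and in fry (adjusted p = 0.011), which asks whether members move one way. H2-Eb1 alone passed over all genes, while 4 members were higher adjusted over the list alone. A 2-sided exact permutation test of the list mean gave p = 0.0286, the smallest that the 70 splits can give (adjusted p = 0.83 over the 29 lists). Splits made within runs gave exact permutation p = 0.0556, which is the smallest that these 36 splits can give. Cd74, the invariant chain that guides class II molecules to their peptides, measured 1.55 ± 0.32 (limma adjusted p = 0.672), H2-Ab1 0.86 ± 0.26 and H2-Aa 0.77 ± 0.25, and H2-Ob went against the list with -0.11 ± 0.11. Another H2-Aa probe set gave -0.11, and other H2-Ab1 probe sets 0.17 to 0.34.

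The class II shift was 0.62 in run 1 to 11 and 0.51 in run 12 to 19, and 0.56 with the run as a covariate (camera adjusted p = 4.32e-06). H2-Eb1 was 0.84 and 0.86 higher within the runs, and its limma adjusted p was 0.00611 with the run as a covariate. H2-Eb1 kept its call without any 1 array, with adjusted p values up to 0.0429. It lost the call with only these 2 groups in the model (adjusted p = 0.623), with an offset of 1 on the signal (0.815), with arrays centred on the median (0.0576), with a replicate block (0.0717), in title numbers 10 to 19 (0.223), in either run alone (0.198 and 0.193) and under a 2-fold minimum. With the actin difference as a covariate the class II shift was 0.50 ± 0.15 (camera adjusted p = 0.0121) and H2-Eb1 measured 0.81 ± 0.12 (limma adjusted p = 0.0441). Fam217b (1.06 ± 0.15), Fgl2 (1.37 ± 0.19) and Tgm2 (1.06 ± 0.15) also passed in that model and are named after their values were seen.

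Of the other lists, 4 passed camera in vaccinated against wild type tumours, each with adjusted p = 0.834 with an estimated correlation. Macrophage and microglia genes had a mean of 0.22 (adjusted p = 0.0221), with 15 of 20 members higher and 3 of 4 vaccinated arrays above the wild type mean. Aif1 measured 0.23 ± 0.09, C1qc, a complement chain made by macrophages, 0.60 ± 0.27, the mannose receptor Mrc1 0.29 ± 0.13 and Tyrobp 0.74 ± 0.36. The members Trem2 (-0.45 ± 0.28), Cx3cr1 (-0.18 ± 0.23), Tmem119 (-0.17 ± 0.22), Cd14 (-0.07 ± 0.25) and Itgam (-0.02 ± 0.13) went against it. This shift rested on vaccinated replicate 2: without it the shift was 0.0035 (adjusted p = 0.828), and without wild type replicate 1 it was 0.19 (0.0782). Without vaccinated replicate 1 it was 0.33 (0.000185). Lyz2, lysozyme of myeloid cells, had a signal of 659.5 on vaccinated replicate 2 and at most 57.3 elsewhere, and C1qa 135 against at most 2.8; both were named after their values were seen. By run the macrophage shift was 0.45 and -0.0069, and camera adjusted p was 0.0347 with the run as a covariate.

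Interferon gamma response genes had a mean of 0.34 (camera adjusted p = 0.0339), with 14 of 17 members higher, among them Irgm2 at 0.79 ± 0.45, Ifi47 at 0.73 ± 0.42, Gbp6 at 0.96 ± 0.57 and Gbp3 at 0.53 ± 0.36. Cxcl10 (-0.30 ± 0.34), Cxcl9 (-0.12 ± 0.18) and Cd274 (-0.11 ± 0.17) went against that list. MHC class I genes had 0.26 (camera adjusted p = 0.0339), with 11 of 13 higher, including the immunoproteasome subunits Psmb9 at 0.92 ± 0.42 and Psmb8 at 0.65 ± 0.32, H2-K1 at 0.56 ± 0.28 and B2m at 0.25 ± 0.13. Nlrc5 measured -0.06 ± 0.34 and Psme1 -0.04 ± 0.14. Type I interferon genes had 0.26 (camera adjusted p = 0.0373), with 17 of 20 higher, including Ifit3 at 0.56 ± 0.44, Xaf1 at 0.54 ± 0.30, Rtp4 at 0.51 ± 0.42 and Cmpk2 at 0.44 ± 0.34. Bst2 (-0.04 ± 0.25), Ddx58 (-0.0049 ± 0.29) and Mx2 (-0.0038 ± 0.33) were just below 0. The vaccinated arrays above the wild type mean were 4 of 4 for interferon gamma and class I and 3 of 4 for type I interferon.

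All 3 lists turned between runs. In run 1 to 11 the shifts were -0.24 for interferon gamma, -0.23 for class I and -0.45 for type I interferon, and in run 12 to 19 they were 0.91, 0.75 and 0.97. The camera adjusted p values were 0.0677, 0.0347 and 0.0687 with the run as a covariate, and the difference between runs was not tested. Without wild type replicate 3 the shifts were 0.08, 0.04 and -0.03 (camera adjusted p = 0.881, 0.881 and 0.833), and without wild type replicate 1 they were 0.58, 0.51 and 0.54. Calls were also lost without vaccinated replicate 3 for interferon gamma (camera adjusted p = 0.252), class I (0.21) and type I interferon (0.427), and without vaccinated replicate 4 for the same lists (0.334, 0.17 and 0.334). Interferon gamma was not called without wild type replicate 2 (0.0608), class I and type I interferon not without wild type replicate 4 (0.2 for both), and type I interferon not without nude replicate 5 (0.0534). In 2-sided exact permutation tests macrophage, class I, interferon gamma and type I interferon means had p = 0.543, 0.457, 0.4 and 0.571, each adjusted to 0.87. None of these 4 lists passed in fry (adjusted p = 0.836 for each) or with only these 2 groups in the model (camera adjusted p = 0.0557 for each). With the actin difference as a covariate macrophage genes had 0.18 (camera adjusted p = 0.194) and interferon gamma genes 0.37 (0.106) and did not pass, while class I had 0.44 (0.00319), type I interferon 0.34 (0.0464) and DNA replication -0.39 (0.000217). Camera used the preset correlation in that model. Without the covariate, only the class II list passed here with an estimated correlation.

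Genes with the smallest p that were lower but did not pass were Calr, a chaperone of the endoplasmic reticulum (-0.64 ± 0.13), Prl8a9 (-0.41 ± 0.09) and 4931406H21Rik (-0.84 ± 0.19). Dct, a melanin synthesis enzyme and a glioma and melanoma antigen, measured 6.87 ± 0.57 (SD, n = 4) in vaccinated and 5.73 ± 0.50 (SD, n = 4) in wild type tumours, a difference of 1.14 ± 0.31 that did not pass limma (adjusted p = 0.756). Fabp7, a lipid carrier of radial glia, measured 0.83 ± 0.22 (limma adjusted p = 0.756). T cell genes had a list mean of -0.01, a median of 0.02 and a camera direction of down, with Cd3e at 0.02 ± 0.26 and Cd8a at -0.40 ± 0.30. For DNA replication the mean was 0.0054, while the median was -0.03 and camera's direction was down.

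**Figure D2:**
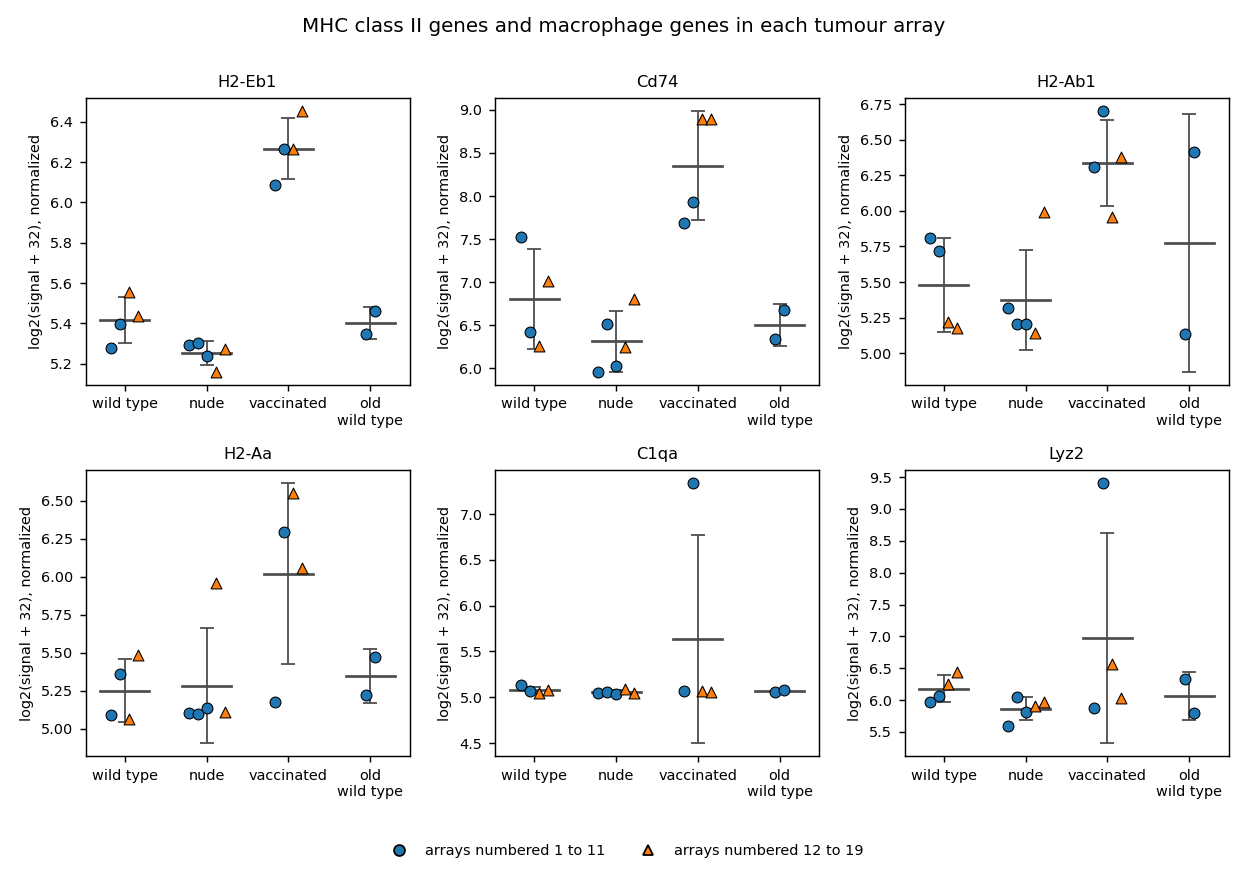
Log2(signal + 32) of single genes on each array, by group; points are arrays (circles numbered 1 to 11, triangles 12 to 19), lines are group means and bars are SD. H2-Eb1 averaged 6.27 in vaccinated tumours against 5.42 in wild type and 5.25 in nude tumours.

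Vaccinated against nude tumours set an immunised host beside one with few T cells. H2-Eb1 rose by 1.01 ± 0.10, from 5.25 ± 0.06 (SD, n = 5) to 6.27 ± 0.15 (SD, n = 4), and Cd74 rose by 2.04 ± 0.31, from 6.31 ± 0.35 (SD, n = 5) to 8.35 ± 0.63 (SD, n = 4). Taf15, a member of the FET family of RNA-binding proteins, fell by 1.26 ± 0.19, from 7.09 ± 0.29 (SD, n = 5) to 5.83 ± 0.21 (SD, n = 4). These 2 genes higher and 1 lower passed limma, with adjusted p = 0.000276, 0.0394 and 0.0394, and 1102 genes had an unadjusted p under 0.05. For each, all 4 vaccinated arrays lay beyond all 5 nude arrays. The sizes depended on the offset and over the alternatives ranged from 0.37 to 2.71 for H2-Eb1, 1.28 to 2.63 for Cd74 and -2.05 to -0.61 for Taf15. A second Taf15 probe set gave -0.33.

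The limma adjusted p values with the run as a covariate were 0.00039 for H2-Eb1, 0.0378 for Cd74 and 0.0106 for Taf15. Within run 1 to 11 and run 12 to 19 the log2 fold changes were 0.90 and 1.14 for H2-Eb1, 1.64 and 2.36 for Cd74, and -1.42 and -1.0 for Taf15. H2-Eb1 kept its call without any 1 array. Cd74 and Taf15 each lost theirs in 13 of the 15 fits without 1 array, with log2 fold changes of 1.86 to 2.26 for Cd74 and -1.34 to -1.16 for Taf15 and adjusted p values up to 0.282 for both. Run 12 to 19 alone gave 43 genes higher and 33 lower, with Cd74 among them (limma adjusted p = 0.0498) but neither H2-Eb1 (0.0637) nor Taf15 (0.168), and run 1 to 11 alone gave 0 and 0. With the actin difference as a covariate H2-Eb1 measured 0.98 ± 0.12 (limma adjusted p = 0.0124) and Fgl2, named after its values were seen, 1.29 ± 0.19 (0.0483), whereas Cd74 at 2.11 (0.372) and Taf15 at -0.93 (0.373) did not pass.

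The class II list was 0.62 higher, with 7 of 9 members higher (camera adjusted p = 3.82e-06; adjusted p = 0.0689 with an estimated correlation; fry adjusted p = 0.00376). Besides H2-Eb1 and Cd74, H2-Ab1 measured 0.97 ± 0.25 and H2-Aa 0.74 ± 0.24, while H2-Oa (-0.17 ± 0.14) and H2-Ob (-0.12 ± 0.11) went against it. Over all genes 2 members passed, and 4 adjusted over the list alone. Its 2-sided exact permutation p was 0.00794, the smallest possible (adjusted 0.115 over the 29 lists), and 0.0167 within runs, the smallest that those 60 splits can give. By run the shift was 0.75 and 0.43, and the camera adjusted p was 1.76e-05 with the run as a covariate, 0.466 in run 12 to 19 alone and 0.157 in title numbers 10 to 19. With the actin difference as a covariate the shift was 0.56 ± 0.14 (camera adjusted p = 0.00646), and the class I list passed too, at 0.33 (0.0104). Both values are for the preset correlation, and without the covariate 0 lists passed in this comparison with an estimated correlation.

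Cell division genes were higher in vaccinated than in nude tumours as groups. Mitosis genes had a mean of 0.46 with 19 of 19 members higher (camera adjusted p = 4.19e-11) and DNA replication genes 0.52 with 20 of 21 higher (1.04e-10), and both had adjusted p = 0.391 with an estimated correlation. Members included the kinase Aurka at 0.51 ± 0.17, Ube2c at 0.44 ± 0.14, Nusap1 at 0.55 ± 0.21 and Ttk at 0.69 ± 0.27. Fen1, which trims Okazaki fragments, measured 0.76 ± 0.27, the polymerase subunit Pola1 0.67 ± 0.24, the helicase subunit Mcm4 0.65 ± 0.25 and Ccne1 0.59 ± 0.22, whereas Tyms was at -0.41 ± 0.39. Other probe sets of Aurka (-0.19) and Ttk (-0.31) had the opposite sign. The vaccinated arrays above the nude mean were 3 of 4 for mitosis and 4 of 4 for replication. By run the shifts were 0.12 and 0.82 for mitosis and 0.28 and 0.80 for replication, with camera adjusted p = 1.75e-10 and 1.07e-09 with the run as a covariate. In run 1 to 11 alone neither list passed (camera adjusted p = 0.669 for mitosis and 0.226 for replication), and in run 12 to 19 alone both did (5.75e-20 and 1.64e-22). The actin difference was lower on every vaccinated than on every nude array and highest on nude replicate 2. With it as a covariate the mitosis shift was 0.20 ± 0.23 (camera adjusted p = 0.0104) and the replication shift 0.13 ± 0.24, which did not pass (0.139). With the actin difference and the run both as covariates, the mitosis shift was 0.15 ± 0.26 and the replication shift -0.051 ± 0.23. The replication shift was 0.33 without nude replicate 2. Exact permutation p was 0.127 for mitosis and 0.119 for replication, both adjusted to 0.392.

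Macrophage genes had a mean of 0.27 (camera adjusted p = 0.000767; adjusted p = 0.391 with an estimated correlation), with 15 of 20 members and 3 of 4 vaccinated arrays higher. Mrc1 measured 0.51 ± 0.13, the F4/80 gene Adgre1 0.61 ± 0.20, C1qc 0.65 ± 0.25 and P2ry12 of microglia 0.28 ± 0.11. Trem2 (-0.16 ± 0.26), Csf1r (-0.13 ± 0.19), Cd14 (-0.08 ± 0.24), Fcgr1 (-0.05 ± 0.17) and Itgam (-0.05 ± 0.13) went against the list, and 1 member was higher adjusted over the list alone. Without vaccinated replicate 2 the shift was 0.05 (camera adjusted p = 0.37). By run it was 0.48 and 0.04, with camera adjusted p = 0.00164 with the run as a covariate, 0.755 in run 12 to 19 alone and 0.0249 with the actin difference as a covariate, and exact permutation p was 0.135 (adjusted 0.392). Neuron genes had a mean of 0.14 (camera adjusted p = 0.00357; adjusted p = 0.199 with an estimated correlation), with 16 of 18 members and 3 of 4 arrays higher. Syt1, a calcium sensor of synaptic vesicles, measured 0.48 ± 0.16, Nrgn 0.38 ± 0.15, Snap25 0.26 ± 0.12 and Gad2 0.24 ± 0.11, with Eno2 at -0.53 ± 0.27 and Tubb3 at -0.14 ± 0.28. By run the neuron shift was 0.10 and 0.17, and the camera adjusted p was 0.00748 with the run and 0.0299 with the actin difference as a covariate. The neuron list did not pass in run 1 to 11 alone (camera adjusted p = 0.0761), in run 12 to 19 alone (0.252) or in title numbers 10 to 19 (0.12). With the neuron and oligodendrocyte mean as a covariate it had camera adjusted p = 0.0909, but that covariate holds the neuron genes themselves, so a weaker result was built in. Nor did the list pass with the title numbers as a covariate (camera adjusted p = 0.0595), with the mean of a gene's probe sets (0.052) or in fry (adjusted p = 0.0842). Its exact permutation p was 0.0476 (adjusted 0.276) and 0.0667 within runs. T cell transcripts did not pass, with Cd3e at 0.30 ± 0.25, Cd4 at 0.03 ± 0.08 and Cd8a at -0.16 ± 0.28.

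Old wild type against wild type tumours addressed the age of the host, with 2 arrays against 4. The age of the wild type hosts is not in the titles, so the size of the age difference is not known here. Type I interferon genes were higher in old hosts, with a mean of 0.72 and 20 of 20 members higher. Interferon gamma genes had 0.47 with 13 of 17 higher, MHC class I genes 0.32 with 13 of 13 higher, and hypoxia and glycolysis genes were lower, at -0.24 with 15 of 19 lower. Both old arrays lay on that side of the wild type mean in all 4 lists. The camera adjusted p values were 7.91e-10 for type I interferon and 0.00838 for the other 3 lists, and each had adjusted p = 0.956 with an estimated correlation. No member passed over all genes, and 0 passed adjusted over the list alone.

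Among type I interferon genes Rtp4 measured 1.14 ± 0.51, Ifit1 1.08 ± 0.49, Rsad2 1.03 ± 0.42 and Oasl1 0.61 ± 0.29. The interferon gamma list held the chemokine Cxcl10 at 1.15 ± 0.41 and the GTPases Gbp3 at 0.99 ± 0.45, Iigp1 at 0.97 ± 0.54 and Irgm1 at 0.70 ± 0.42, and Irf8 (-0.35 ± 0.27), Ido1 (-0.25 ± 0.16), Cxcl9 (-0.12 ± 0.22) and Nos2 (-0.01 ± 0.08) went against it. Class I members included Psmb9 at 0.77 ± 0.52, H2-D1 at 0.60 ± 0.34, B2m at 0.32 ± 0.16 and Tapbp at 0.28 ± 0.21. Of the glycolytic enzymes, Hk2 measured -0.64 ± 0.30, Pfkp -0.55 ± 0.27 and Aldoa -0.47 ± 0.16, and Egln3, an oxygen-sensing hydroxylase, -0.41 ± 0.18. Ankrd37 (0.45 ± 0.37), Pdk1 (0.15 ± 0.31), Pgk1 (0.06 ± 0.09) and Pfkfb3 (0.05 ± 0.35) went against that list. Ccl5 measured 1.79 ± 0.41 and did not pass limma (adjusted p = 0.703).

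Both old arrays were in run 1 to 11, where the shifts were 0.27 for type I interferon, 0.12 for interferon gamma, -0.07 for class I and -0.28 for hypoxia. With the run as a covariate they were 0.66, 0.45, 0.21 and -0.26, with camera adjusted p = 3.68e-06, 0.0509, 0.169 and 0.0232. Without wild type replicate 3 the shifts were 0.43 for type I interferon (camera adjusted p = 0.000188), 0.22 for interferon gamma (0.505) and 0.09 for class I (0.599). Without old wild type replicate 2 they were 0.29 for interferon gamma (0.499) and 0.11 for class I (0.661), and without old wild type replicate 1 class I was 0.53 (0.00026). Leaving out wild type replicate 1 gave 0.71 for interferon gamma and 0.56 for class I. Hypoxia lost its call without old wild type replicate 1 (-0.19, camera adjusted p = 0.0509), old wild type replicate 2 (-0.29, 0.0662) or wild type replicate 2 (-0.18, 0.0854). An exact permutation test of 15 splits cannot go below 0.0667, and it gave 0.267, 0.4, 0.533 and 0.133 (adjusted 0.921 for all 4). With the actin difference as a covariate hypoxia lost its call (-0.16, camera adjusted p = 0.127), while interferon gamma (0.50, 0.0375), class I (0.44, 0.000838) and type I interferon (0.78, 8.48e-08) kept theirs and mitosis passed at -0.26 (0.00954). These calls are for the preset correlation, and without the covariate 0 lists passed here with an estimated correlation.

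Neu3, a ganglioside sialidase, rose by 0.59 ± 0.08 in old wild type tumours, from 5.07 ± 0.02 (SD, n = 4) to 5.66 ± 0.05 (SD, n = 2), and Slc46a1, a folate transporter, rose by 0.82 ± 0.12, from 5.22 ± 0.07 (SD, n = 4) to 6.04 ± 0.22 (SD, n = 2). These were the 2 genes that passed limma (adjusted p = 0.0308 and 0.0423), both old arrays lay above all 4 wild type arrays for each, 0 genes fell, and 826 had an unadjusted p under 0.05. Their signals were at the floor in wild type hosts (0.9 to 2.1 for Neu3, 3.3 to 7.1 for Slc46a1) and low in old hosts (15.4 and 18.1, 24.4 and 38.4), so the sizes were set by the offset and ranged over the alternatives from 0.18 to 2.96 for Neu3 and 0.28 to 2.48 for Slc46a1. A second Slc46a1 probe set gave 0.10. Neither passed with the run as a covariate (adjusted p = 0.079 and 0.153) or with the actin difference as a covariate (0.16 and 0.221), and within run 1 to 11 the fold changes were 0.59 and 0.83. Without 1 array, Neu3 lost its call in 12 of 15 fits (0.55 to 0.62, adjusted p up to 0.249) and Slc46a1 in 14 of 15 (0.66 to 0.97, adjusted p up to 0.635). The lowest p values that did not pass belonged to Gpc1, a heparan sulfate proteoglycan (-0.67 ± 0.15), Dhcr7, a late enzyme of cholesterol synthesis (-1.03 ± 0.23) and Pcare (-0.63 ± 0.15).

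The fold changes of nude and of old wild type tumours, both against the same wild type arrays, correlated with r = 0.37 across 18193 genes (Spearman 0.38), and genes are not independent replicates. Simulated data with no differences gave r of 0.41 to 0.46 from the shared wild type arrays alone. With the 4 wild type arrays split so that each comparison had its own 2, the mean r over the 6 ways was -0.05 (-0.34 to 0.11). In some ways the wild type arrays of the nude and of the old comparison came from different runs. Differences between runs therefore enter these values too. With the run as a covariate r was 0.23, below the 0.41 to 0.45 that simulated data with no differences gave in that model, and with the actin difference as a covariate it was 0.53, above the 0.38 to 0.43 simulated there. The simulated noise was independent between genes and arrays, so neither gap measures an effect of the hosts.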

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

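All tests of explanations here were chosen after the results were seen, except the counts over splits drawn without regard to the run. In 7 of 132 groups of arrays, 1 array stood apart from the others, and chance flags about 1 in 20 groups, or 6.6 here.

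The astrocyte list measured 7.81 on nude replicate 4, with the nearest nude array at 7.63. The endothelial list measured 6.39 on vaccinated replicate 4 (nearest 6.47). The mitosis list measured 10.43 on wild type replicate 2 (nearest 10.65). The sex-linked list measured 5.62 on nude replicate 5 (nearest 5.42) and 5.41 on vaccinated replicate 2 (nearest 5.62). Cd4 measured 5.38 on wild type replicate 2 (nearest 5.15), and Prom1, the CD133 gene, 5.30 on wild type replicate 1 (nearest 5.08).

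The mean of the class II genes was higher on all 4 vaccinated arrays, though not every member was. Macrophages like those of vaccinated replicate 2 would have to bring their other transcripts too. In the 3 other vaccinated arrays the macrophage list shifted by 0.0035 ± 0.069 (SE), where the class II genes would need 0.51. That need takes the whole class II rise of replicate 2 as theirs. The rise includes Ctss (signal 385.5, at most 33.8 elsewhere), while H2-Eb1 on replicate 2 (43.2) lay between the other vaccinated arrays (31.8 to 53.7). The comparison thus bears only on macrophages like those, and class II expression by other macrophages was not tested. The labelling run is argued against as the whole cause by the class II shifts of 0.62 and 0.51 within the runs. The 0.56 ± 0.12 with the run as a covariate adds nothing, because both groups were balanced over runs. With the actin 3' minus 5' difference as a covariate the shift was 0.50 ± 0.15. That difference parted the groups, so the value extends a slope of -0.39 ± 0.54 (SE) beyond the overlap of the groups. RNA quality therefore stays open. Dendritic cells or B cells stay open, because their lists shifted by 0.034 ± 0.061 and 13 of 15 and 12 of 13 of their genes never exceeded a signal of 100 (highest medians Fscn1 at 6855 and Ighm at 117). The vaccine, the difference that the design names, and class II expression by the tumour cells remain open and untested.

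The type I interferon list passed camera in all 3 comparisons with wild type, but not with an estimated correlation (adjusted p = 0.82 in nude, 0.834 in vaccinated and 0.956 in old wild type tumours). As a covariate the labelling run accounted for 0.012 ± 0.028 (SE) of the shift of 0.36 in nude tumours and 0.060 ± 0.14 of the shift of 0.72 in old wild type tumours. Nude and wild type arrays were nearly balanced over runs, and vaccinated and wild type arrays fully. A run effect equal in all groups could therefore account for little or nothing there. Both old arrays were in run 1 to 11, and their estimate assumes such an equal effect, although in nude and vaccinated tumours the list turned between runs. The run thus stays open in old wild type tumours. In run 1 to 11 alone the shifts were -0.10 ± 0.48, -0.45 ± 0.40 and 0.27 ± 0.43 in nude, vaccinated and old wild type tumours, too wide to decide. Wild type replicate 3 had the lowest list mean at 7.44 and replicate 1 the highest wild type mean at 9.15. Low interferon genes on replicate 3 may carry part of the difference and stay open, since without it the shifts were 0.068 ± 0.32, -0.034 ± 0.29 and 0.43 ± 0.38, and the hosts themselves remain open and untested.

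DNA replication and mitosis genes were lower in nude than in wild type tumours by a mean of -0.45 over both lists, and lower than in vaccinated tumours by -0.49. Nude and wild type arrays were nearly balanced over runs, so a run effect equal in all groups could account for little of the shift against wild type. The part of -0.013 ± 0.019 (SE) that it took, leaving -0.44 ± 0.23 with the run as a covariate, therefore adds nothing. Within run 1 to 11 the shift was -0.25 ± 0.47, too wide to decide, and in the other run it was -0.69. A run effect that differs between groups thus stays open. The actin difference had group means of 0.38 in both nude and wild type tumours. An effect of RNA quality read from it, with 1 slope for all groups, could thus account for little there (0.0079 ± 0.0032 of the shift). RNA quality stays open against vaccinated tumours, where it accounted for -0.32 ± 0.13 and left -0.16 ± 0.23. A single array stays open against wild type: without 1 array the value closest to 0 was -0.29 ± 0.20, which its spread does not part from a much smaller shift. The nude host, which the design names, stays open and untested, and so does the spread between arrays, since neither list passed with an estimated correlation.

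Other splits of the same arrays, drawn without regard to the run, did not exclude chance for any count above 0, with the real split counted among them. In nude against wild type tumours the real count of 0 genes tests nothing, since 100 of 100 splits must reach it (highest other 1205), and 69 of 100 gave at least the real 3 lists (highest other 8). In vaccinated against wild type tumours 4 of 35 splits gave at least the real 1 gene (highest other 485) and 15 of 35 at least the real 5 lists (highest other 9). In vaccinated against nude tumours the numbers were 5 of 100 splits for the real 3 genes (highest other 314) and 31 of 100 for the real 5 lists (highest other 8). The splits with 1205, 485 and 314 genes set one labelling run against the other, which points to the run as a structure of the samples. With the run as a covariate the real comparisons gave 0, 1 and 3 genes in the same order.

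All splits with the same run balance as the real one were then counted, a test chosen after the counts above were seen. For the 3 genes of vaccinated against nude tumours, 2 of 60 such splits gave as many, a share under 0.05. With the run as a covariate 3 of 60 did, which is not under 0.05. These counts were chosen late and not adjusted for their number, so they do not exclude chance. The highest other counts, 166 and 472 genes, came from a split that keeps the run balance, so the run is not the only structure of the samples. The 5 lists of that comparison were reached by 17 of 60 splits (highest other 8), and by 15 of 60 with the run as a covariate (highest other 8), so chance was not excluded. Nor was it for the lists of nude against wild type tumours, where 43 of 60 splits gave the real 3 lists (highest other 8) and, with the run as a covariate, 31 of 60 the real 4 lists (highest other 9). Its real 0 genes again test nothing, as 60 of 60 splits must reach them (highest other 4, or 97 with the run as a covariate). In vaccinated against wild type tumours the 18 splits are too few for a share under 0.05. The real 1 gene had a highest other of 1, with 2 splits as high both without and with the run as a covariate. The real 5 lists had a highest other of 9 (8 splits as high), and the 3 lists with the run as a covariate a highest other of 8 (14 splits as high).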

How the results depend on the processing

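The labelling run and actin settings were chosen after seeing the data, and the other settings before. Signal over background limits the T cell list, in which 16 of 17 genes never exceeded a signal of 100, whereas 10 of 13 class I genes were always above it. It limits the class II list too. There 6 of 9 genes never exceeded 100, 0 were always above it, and the median over genes was 16.8. The class II shift in vaccinated against wild type tumours passed in all 35 alternatives (0.29 to 1.03, adjusted p up to 0.0438), H2-Eb1 there in 25 of 33 (adjusted p 0.00204 to 0.815), and H2-Eb1 against nude in 30 of 33. Cd74 against nude passed in 8 of 34, Taf15 in 8 of 33, Neu3 in 6 of 32 and Slc46a1 in 3 of 32. For 276 gene results, 9236 alternatives were run, and 8838 kept both the direction and the side of the threshold. In 278 the direction changed without a call in either fit, and in 0 it changed with a call. A call was lost in 117 and gained in 3. For 23 list shifts, 816 alternatives were run, and 670 kept both. A call was lost in 112, and in 25 the direction changed without a call in either fit. The other 9 reversed, which means that the direction changed with a call in at least 1 fit. Except where noted, the cause of a change was not tested. The labels do not say whether replicate numbers pair the arrays. Deviations from the group mean correlated between arrays with the same number from -0.07 to 0.54 in nude and 0.04 to 0.22 in vaccinated against wild type. They correlated from -0.09 to 0.17 in vaccinated against nude. The same number gave the highest r in 3 of 4 pairs of nude against wild type and in 1 of 4 pairs of either vaccinated comparison. In old wild type against wild type r was -0.43 to 0.14, but deviations of 2 arrays mirror each other, so this tests nothing.

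Without 1 array, lists past the threshold ranged over 3 to 6 (nude against wild type), 2 to 8 (vaccinated against wild type), 1 to 6 (old against wild type) and 4 to 8 (vaccinated against nude). Genes higher were 0 to 0, 1 to 1, 0 to 2 and 1 to 3, and genes lower 0 to 1, 0 to 1, 0 to 0 and 0 to 1, in that order. The agreement of nude and old fold changes was 0.16 to 0.56 (main value 0.37), where the lone old array is assumed to vary like the others. It was 0.23 with the run as a covariate, 0.53 with the actin difference as a covariate and -0.046 with controls split in 2 and 2. That split removes the shared arrays by construction, but differences between runs enter it.

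Lists in nude against wild type (3) were 5 with arrays centred on the median, the brighter genes, the neuron and oligodendrocyte mean as covariate, and only the 2 groups compared; 0 with an estimated correlation in camera and in fry; 8 in run 12 to 19 and 7 in title numbers 10 to 19. Genes there were 11 higher and 8 lower in run 12 to 19.

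Lists in vaccinated against wild type (5) were 3 with array weights, the run as covariate and only run 1 to 11; 2 with the larger offset; 1 at adjusted p under 0.01, with an estimated correlation, in fry, with the neuron and oligodendrocyte covariate, with only the 2 groups compared and with a replicate block. Genes higher (1) were 4 with the actin difference as a covariate, and 0 with arrays centred on the median, at least a 2-fold change, the brighter genes (where H2-Eb1 is too dim to be tested), an offset of 1, run 1 to 11, only the 2 groups, title numbers 10 to 19 and a replicate block.

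Lists in old against wild type (4) were 0 with an estimated correlation, in fry, in run 1 to 11 and in title numbers 1 to 9; 2 with only the 2 groups; 1 with title numbers as covariate. Genes higher (2) were 1 with the mean of a gene's probe sets and 0 at adjusted p under 0.01, with arrays centred on the median, a 2-fold change, the brighter genes, deposited scaling, the run, the actin difference, the neuron and oligodendrocyte mean or the title numbers as covariate, no intensity trend, an offset of 1, run 1 to 11, only the 2 groups, title numbers 1 to 9 and a replicate block.

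Lists in vaccinated against nude (5) were 2 with the brighter genes, 0 with an estimated correlation, 1 in fry, and 3 in run 1 to 11 and in run 12 to 19. Genes higher (2) were 1 at adjusted p under 0.01, with deposited scaling, every probe set, the mean of probe sets, the neuron and oligodendrocyte or title number covariate, no intensity trend, the larger offset, only the 2 groups and a replicate block; 0 with the brighter genes, run 1 to 11 and title numbers 10 to 19; 43 in run 12 to 19. Genes lower (1) were 0 with the actin difference as a covariate and under these same settings except no intensity trend and run 12 to 19, which gave 33.

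Reversed shifts were, in run 1 to 11, interferon gamma (-0.24), class I (-0.23) and type I interferon (-0.45) in vaccinated against wild type, class I in old wild type (-0.066, also with title numbers 1 to 9) and type I interferon in nude (-0.10, also with title numbers 1 to 9). Macrophage genes in vaccinated against wild type reversed in run 12 to 19 (-0.0069), and type I interferon there without wild type replicate 3 (-0.034).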

Other observations

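The look at myeloid genes on vaccinated replicate 2 was chosen after the result was seen, as was the run as a covariate, and the other tests of the lists, Dct and Pmel followed rules set before. Genes of protein synthesis, respiration and cell division had high signals in the tumours, although signals of different probe sets do not rank abundance. Ribosomal protein genes had a median signal of 9112, genes of oxidative phosphorylation 3549, mitosis genes 1371 (Cdc20 at 6065) and DNA replication genes 1284 (Pcna at 6755), against 93.8 for the median gene. Matrix and invasion genes had a median of 661, with Sparc, a matrix glycoprotein, at 8802 and 3 of 19 genes never above 100. Glial genes were mixed: Mbp, the myelin basic protein gene, stood at 7996 and Fgfr3 at 3096, whereas 6 of 13 astrocyte genes never exceeded 100. Among melanocyte lineage antigens, Gpnmb had a median of 4290. Of the host cell markers, choroid plexus genes had a median of 13.4, neuron genes 9.25, endothelial genes 16.7, erythroid genes 3.7 and neutrophil genes 11.7. Single members of these lists stood higher, such as Angpt2 of the endothelial list at 619 and Tubb3 of the neuron list at 383.

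Of the 29 lists, 20 passed camera in none of the 4 comparisons in the model without covariates, with shifts between -0.12 and 0.28. With the run as a covariate 2 of them passed camera, immediate early and stress genes in nude against wild type tumours (0.20, adjusted p = 0.0122) and melanocyte antigens in old wild type against wild type tumours (0.37, 0.0409). Both calls are for the preset correlation, and without the run 0 lists passed in either comparison with an estimated correlation. Without it the smallest adjusted p values were 0.0511 for immediate early and stress genes, 0.0872 for melanocyte antigens, 0.109 for checkpoints and regulatory T cells, 0.111 for dendritic cells, 0.136 for extracellular matrix and 0.218 for ribosomal proteins. They were 0.222 for choroid plexus, 0.285 for astrocytes, 0.306 for chemokines, 0.309 for sex-linked genes, 0.372 for erythroid cells, 0.442 for oligodendrocytes, 0.458 for neutrophils and 0.627 for T cells. The others had 0.681 for oxidative phosphorylation, 0.764 for endothelial cells, 0.777 for cytotoxic lymphocytes, for pericytes and for neural stem genes, and 0.827 for B cells. In old wild type tumours Dct measured 1.19 ± 0.38 (limma adjusted p = 1), near its 1.14 ± 0.31 in vaccinated tumours, both against wild type. Pmel, another melanosome gene, measured 0.63 ± 0.28 in vaccinated against wild type tumours (limma adjusted p = 0.97).

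The neuron list was lower in nude than in wild type tumours by -0.12, with a 2-sided exact permutation p of 0.00794, the smallest possible, which became 0.23 over the 29 lists. The choroid plexus list was 0.12 higher in vaccinated than in nude tumours, with the same exact permutation p, adjusted to 0.115. Both lists were near the floor.

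Vaccinated replicate 2 stood apart from the other 14 arrays in several myeloid transcripts. Lyz2 had a signal of 659.5 against at most 57.3 elsewhere, the protease gene Ctss 385.5 against 33.8, C1qb 243.6 against 42.9, Tyrobp 168.5 against 25.8 and C1qa 135.3 against 2.8. Csf1r, the receptor that macrophages need, was at 100 on that array, within the 81.1 to 158 of the 11 arrays outside the vaccinated group. These genes were chosen after their values were seen.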
